A study of Mus musculus with 6 samples.

How the data were processed

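Ovarian tissue of rats was sequenced in 6 libraries, 3 from controls and 3 from animals exposed to PM2.5. Per the labels' protocols, RNA was extracted with Trizol, kept at an integrity number above 7, selected for poly(A), copied with dUTP so that strand was marked, and sequenced from both ends on an Illumina NovaSeq instrument. Per the submitters' processing notes, the tools named were cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, without their roles. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes may not be separated.

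The deposited table gives a count and an FPKM value per gene and library, per the file headers, for 22487 genes. The count columns, as deposited by the authors, hold whole numbers that sum to between 47662338 and 60749578 per library. Values from 1 to 20 were multiples of 4 in 31.8 to 33.9% of cases, where 25% would be chance, and the reason is not given. The FPKM columns are the authors' own normalisation per kilobase and per library total and were used only to filter genes and in alternatives. Of the genes, 2551 had no name and 168 shared a name with another, and for a shared name the row with most counts stood for a list member. A reference annotation of the mouse was not used here.

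The plan had been a limma test on log2(FPKM + 1), with edgeR on counts if the table held whole counts. Since it did, edgeR 4.0.16 in R 4.3.3 was used on the counts as deposited, with TMM factors, glmQLFit and glmQLFTest for PM2.5 over control, and the limma 3.58.1 test became an alternative. Genes needed a mean of at least 0.5 FPKM over the 6 libraries. P-values were two-sided and adjusted by Benjamini-Hochberg at 0.05. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values use TMM factors, and list scores add a prior count of 2 before the log2. A gene with no counts in a group was set against a floor of 3 counts per library, which covers counting error only.

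The 28 gene lists and 21 marker lists were fixed before the data were examined and tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry. Lists needed 5 tested members. The genes named follow a rule fixed beforehand: the 12 largest rises and the 12 largest falls among named genes with an adjusted p below 0.05, a mean of at least 1 FPKM and groups that do not overlap, up to 4 members with the smallest p of each list described, and 27 genes of ovarian and stress biology whatever their values. A few other genes are named where they stand out, and those were chosen after their values were seen. Some genes that the rule names are not reported here.

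The pipeline was tested on simulated counts for the 15303 genes of this comparison. Of these, 200 with a mean of at least 1 FPKM were changed 2-fold to 16-fold, and a further small list was lowered. Genes were simulated independently of each other, so movement shared between genes in these samples was absent. edgeR recovered 8% of genes changed 2-fold, 76% of those changed 4-fold, 84% of those changed 8-fold and 96% of those changed 16-fold. Of its 144 calls, 12 were genes that had not been changed. Chi-square values per degree of freedom between libraries of a group were 112 or more, so no library repeats another. Alternatives were other filters, scalings, pseudocounts and tests (including DESeq2 1.42.0), a replicate block and leaving out each library.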

Results

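RNA sequencing measured gene expression in ovarian tissue of adult female rats in 2 groups, animals exposed to PM2.5 (fine airborne particulate matter) from a cowshed and untreated controls, with 3 libraries in each group. Every sample title carries 30 days, without saying what the days count. The organism field of the labels names the mouse, while the titles name the rat and all 22487 gene identifiers in the deposited table are rat Ensembl identifiers, so the samples are treated as rat. The total count per library was 47662338, 49525247 and 51530427 in controls 1 to 3 and 53043998, 60749578 and 49554241 in PM2.5 libraries 1 to 3. Between 19258 and 19841 genes had a count in a library, and 15303 genes with a mean of at least 0.5 FPKM were tested. The labels do not say whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between these samples.

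The comparison asks how the ovary differed after exposure to cowshed PM2.5. The globin genes Hba-a1 and Hbb and the heme synthesis gene Alas2 rose, as did the genes of haptoglobin and relaxin, and a larger set of genes fell, among them the stress chaperone Hspa1b, the cell surface receptor Cd44 and the guidance factor Sema3d. Hp, which encodes the hemoglobin-binding plasma protein haptoglobin, rose from 93.8 ± 28.3 to 1123 ± 317 CPM (counts scaled to a common library total, mean ± SD, n = 3 in each group). Rln1, which encodes relaxin, rose from 23.2 ± 18.9 to 462 ± 86.0 CPM, and Miox, which encodes the enzyme that opens the myo-inositol ring, rose from 1.24 ± 0.659 to 51.7 ± 43.3 CPM. Txnip, an inhibitor of thioredoxin, rose from 351 ± 34.3 to 1078 ± 245 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold changes were 3.58 ± 0.34 (SE) for Hp, 4.32 ± 0.64 for Rln1, 5.38 ± 0.77 for Miox and 1.62 ± 0.21 for Txnip, with adjusted p between 0.0434 and 0.0442.

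Cd44, the receptor for hyaluronan, fell from 108 ± 51.0 to 10.1 ± 1.67 CPM, and Sema3d, a secreted semaphorin, fell from 149 ± 78.8 to 7.67 ± 3.33 CPM. Manf, a secreted factor induced by endoplasmic reticulum stress, fell from 33.4 ± 17.7 to 2.83 ± 1.08 CPM. Gzmb, which encodes the granzyme B of cytotoxic lymphocytes, fell from 25.1 ± 16.1 to 1.42 ± 0.873 CPM. Aqp3, which encodes a channel for water and glycerol, had 12.1 ± 9.10 CPM in the controls and no count in any PM2.5 library, at least 218-fold lower against a floor of 3 counts per library. Edn2, which encodes the vasoconstrictor endothelin-2, had 58.3, 131 and 6.18 CPM in controls 1 to 3 and 0, 0.0659 and 0 CPM in the PM2.5 libraries. The other named genes that rose most were RT1-CE16, Ccdc92b, Fem1b, Gsta6 and Atr, with log2 fold changes from 1.21 to 2.51, and among those that fell most were Myl1, Septin12, Kctd11 and Odaph, with log2 fold changes from -5.14 to -3.21. Hp lies on chromosome 19 from 37539627 to 37544523, Cd44 on chromosome 3 from 89157058 to 89244620 and Rln1 on chromosome 1 from 227079966 to 227082882, in coordinates of the deposited table, whose genome build is not given in the sources used here. RT1-CE16, Gsta6 and Gzmb belong to families of similar genes, and their values are uncertain where the counting could split reads between copies.

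**Figure D1:**
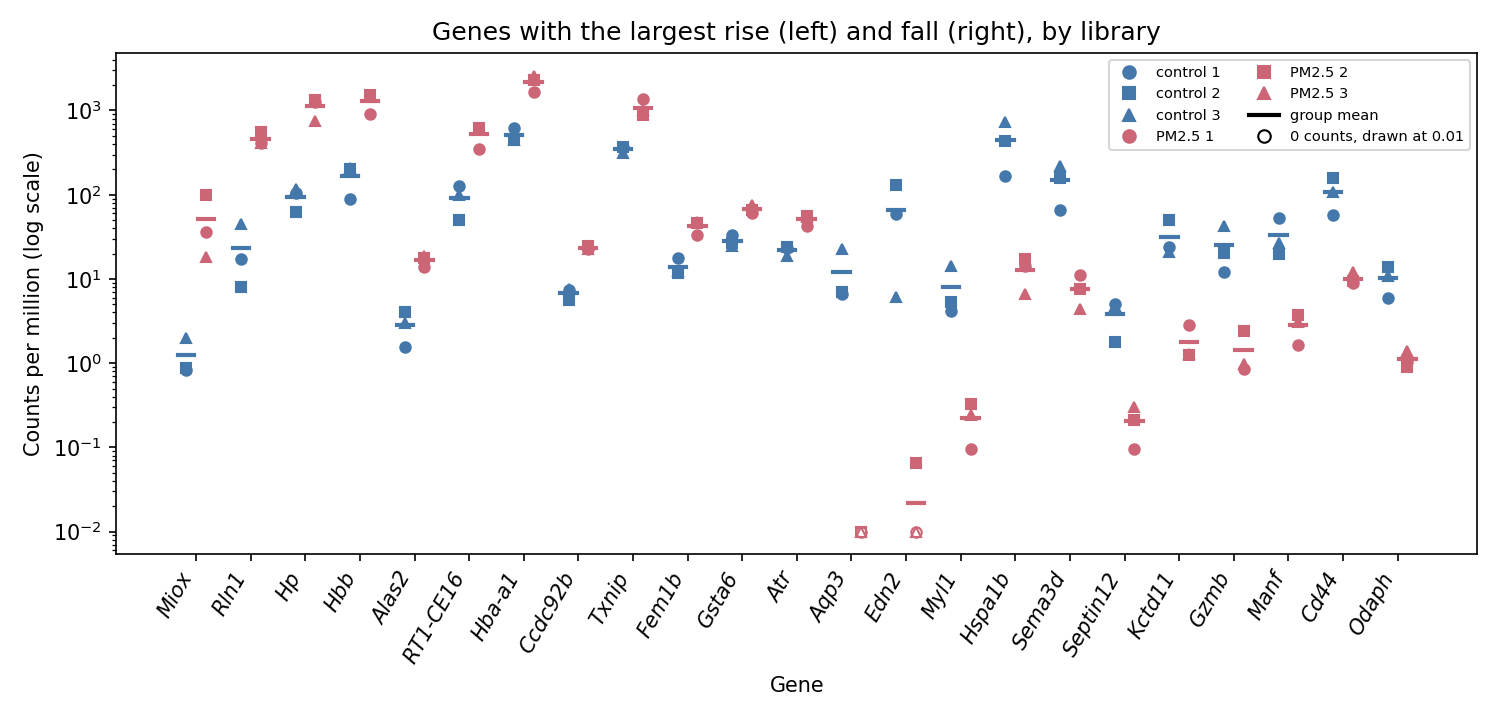
Normalised counts (CPM) on a log axis, by library, for the 12 genes with the largest rise and 11 of the 12 with the largest fall. The ranking is among named genes that passed the adjusted test with a mean of at least 1 FPKM. Points are libraries, bars are group means, and open points mark 0 counts. The PM2.5 libraries of Hp lie at 1123 CPM on average against 93.8 CPM in the controls, and all 3 PM2.5 libraries of Aqp3 lie at 0.

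In all, 142 of 15303 genes changed at an adjusted p below 0.05 in edgeR's quasi-likelihood test, 29 higher and 113 lower in PM2.5, and the groups did not overlap in any of the 142. Groups were apart in 4168 of the tested genes, or 27.2%, where chance gives 10%. Without the adjustment, 1354 genes passed p below 0.05 with at least a 2-fold difference, 525 higher and 829 lower. The count of 142 fell to between 0 and 7 genes when any single library was left out, with 6 higher and 1 lower without PM2.5 library 3, and to 8 without the filter on low values, while DESeq2 called 1767 genes. All 142 kept their sign with DESeq2 and with each library left out where they were tested. Groups that do not overlap made this nearly certain beforehand, so it adds no evidence.

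The immediate early genes, which cells transcribe within minutes of a stimulus, were lower in the PM2.5 libraries as a group, with 15 of 16 measured members below the controls and a median log2 fold change of -2.35. Fos fell from 171 to 24.1 CPM (log2 fold change -2.82 ± 0.40) and Ier3 from 121 to 41.9 CPM, with an adjusted p of 0.0434 for each in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes. These were the 2 members that passed over all genes, and 12 members passed when adjusted over the list alone, among them Fosb at -4.12 ± 0.82 and Atf3 at -2.60 ± 0.55. The list was shifted by camera with a preset correlation (adjusted p = 1.60e-08), and not with an estimated one (adjusted p = 0.792 with an estimated correlation). Control 2 had the highest score on this list, 2.07, against 0.13 and 0.35 in controls 1 and 3, and without control 2 the list median was -1.16 over the 15 members then tested.

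The heat shock genes, which encode chaperones that fold damaged proteins, had 12 of 15 measured members below the controls. Hspa1b fell from 442 ± 279 to 12.7 ± 5.49 CPM, Hspa8 from 2282 to 985 CPM and Dnaja1 from 252 to 115 CPM, and Hsph1 fell with a log2 fold change of -1.32 ± 0.20. Of the 15 members 4 fell over all genes and 6 when adjusted over the list alone, with edgeR's quasi-likelihood adjusted p of 0.0434 for Hspa1b and Dnaja1 and 0.0463 for Hspa8 and Hsph1. Hspa1a, a near-identical copy of Hspa1b that can share its reads, had a log2 fold change of -4.83 ± 1.56 and did not pass over all genes (edgeR's quasi-likelihood adjusted p = 0.159). Cryab at 1.06 ± 0.40, Hsp90ab1 at 0.06 and Hspd1 at 0.20 lay in the opposite direction and did not pass. The list median was -0.37 (camera adjusted p = 1.20e-05, and adjusted p = 0.792 with an estimated correlation).

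Genes of the p53 response and of cell senescence were lower as a group, with 13 of 17 members below the controls and a median log2 fold change of -0.52. Plk2, a kinase induced by p53, fell from 87.4 to 33.8 CPM and was the member that passed over all genes. Adjusted over the list alone 8 members fell, among them Sesn2 at -1.32 ± 0.27. Camera gave an adjusted p of 0.000395 (adjusted p = 0.609 with an estimated correlation). Larger sets on these themes in the table's own annotation were not shifted. The p53 signaling pathway had 67 genes and a median of -0.10 (camera adjusted p = 0.567). Cellular senescence had 151 genes and a median of 0.01 (camera adjusted p = 0.948). Genes of ovulation had a median of -1.01, and camera gave an adjusted p of 0.00370 (adjusted p = 0.792 with an estimated correlation). Edn2 was the member that fell over all genes, and 5 members fell when adjusted over the list alone, among them Areg, an epidermal growth factor receptor ligand, and Rgs2. Control 2 had the highest score on the ovulation list too, 1.96, against -0.02 and 0.16 in controls 1 and 3. Without control 2 the list median was -0.67 over the 14 members then tested, with 8 below the controls and 6 above. The ovulation list shares Egr1 and Nr4a1 with the immediate early list, so the shifts of these lists are not independent. Tnfaip6 at 1.73 ± 0.86 and Ptgs2 at 0.82 ± 1.13, which cumulus cells express at ovulation, lay in the opposite direction and did not pass.

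Among the clock genes Bhlhe40, a transcriptional repressor, fell from 97.7 to 27.3 CPM and was the member that passed over all genes. Adjusted over the list alone, Bhlhe40, Dbp, Per3, Per2 and Tef fell and Bmal1, which drives transcription of the Per genes, rose from 17.1 to 45.3 CPM. The list had 12 of 17 members below the controls (camera adjusted p = 0.0425, and adjusted p = 0.792 with an estimated correlation), and its camera adjusted p was 0.053 without control 3, 0.0587 without PM2.5 library 2 and 0.182 without PM2.5 library 3. All 13 measured transcripts of the mitochondrial genome had negative fold changes, with a median of -0.34, and 2 fell when adjusted over the list alone, Mt-nd5 and Mt-nd6, which encode subunits of respiratory complex I. The estimated correlation between the 13 members was 0.83, so they are not independent observations. The groups overlapped on this list, with a score of 0.03 in PM2.5 library 2 and -0.04 in control 2. Camera gave an adjusted p of 0.0143 (adjusted p = 0.792 with an estimated correlation), which was 0.128 without control 1, 0.0504 without PM2.5 library 1 and 0.141 without PM2.5 library 3, and the median was -0.21 without control 1 and -0.23 without PM2.5 library 3.

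**Figure D2:**
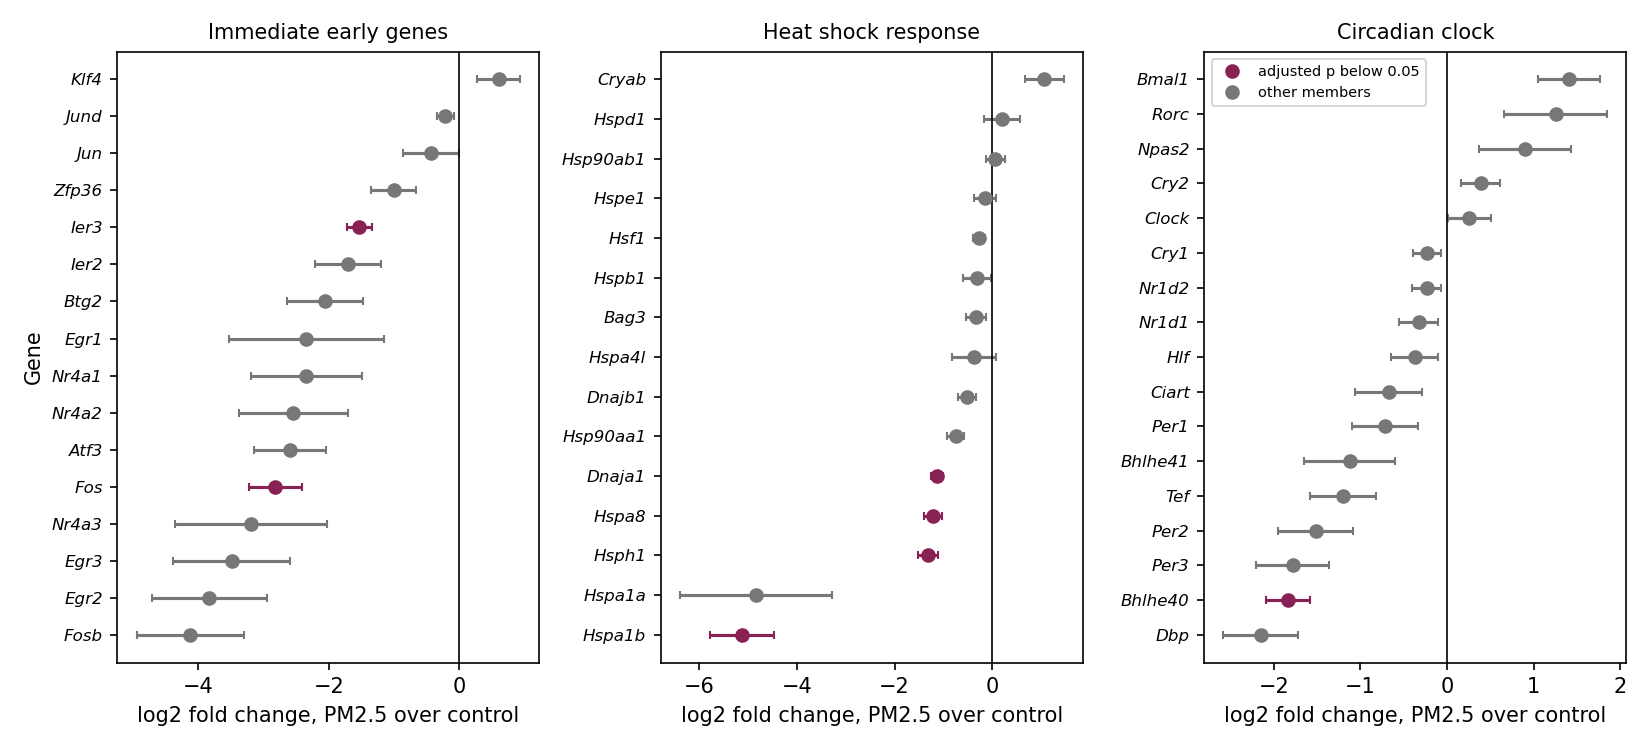
Log2 fold changes of PM2.5 over control for the measured members of the immediate early, heat shock and clock gene lists, with SE as error bars (n = 3 libraries in each group). Members that passed the adjusted test over all genes are drawn in a darker colour. Fos lies at -2.82, Hspa1b at -5.12 and Bmal1 at 1.41.

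Genes of cholesterol synthesis and uptake were lower and genes of the cell cycle higher as groups, without any member that passed over all genes or over the list alone. In the cholesterol list 22 of 24 members were below the controls, with a median of -0.51, such as Idi1 at -1.23 ± 0.38 and Hmgcs1 at -1.63 ± 0.67 (camera adjusted p = 0.0143, and adjusted p = 0.792 with an estimated correlation). In the cell cycle list 27 of 30 members were above the controls, with a median of 0.57, such as Tyms at 1.16 ± 0.32 and Top2a at 0.97 ± 0.53 (camera adjusted p = 0.00182, and adjusted p = 0.792 with an estimated correlation). Both rested on control 3 and PM2.5 library 3, since without control 3 the camera adjusted p was 0.572 for cholesterol and 0.165 for the cell cycle, and without PM2.5 library 3 it was 0.259 and 0.149. Without control 3, 12 of the 24 cholesterol members were below the controls and the cell cycle median was 0.22, and without PM2.5 library 3 the medians were -0.26 and 0.36. Without PM2.5 library 1 the cholesterol median was -0.89, with all 24 members below the controls. Control 3 also had the lowest scores on the granulosa cell list, -0.99, and on the oocyte list, -1.66. PM2.5 library 3 had the highest scores on both, 0.63 and 1.24.

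Steroid hormone synthesis and the main genes of the follicle did not pass the test. Star, which carries cholesterol into the mitochondrion, had 5004 ± 2588 CPM in controls and 2635 ± 1914 CPM in PM2.5, and Cyp11a1, the side-chain cleavage enzyme, had 2578 ± 675 and 4381 ± 2500 CPM. The log2 fold change was -1.55 ± 0.75 for Cyp17a1, -0.47 ± 0.55 for the aromatase Cyp19a1, -0.07 ± 0.44 for Hsd3b1 and 0.77 ± 0.69 for Hsd17b1. Fshr, Lhcgr, Amh, Inha, Gdf9 and Zp3 had log2 fold changes between 0.37 and 0.62, each smaller than its SE. Of 19 steroid synthesis members none passed, over all genes or when adjusted over the list alone (camera adjusted p = 0.632). Akr1c3, an aldo-keto reductase, had 6122 ± 2962 CPM in controls and 1211 ± 859 CPM in PM2.5, with an adjusted p of 0.142 in edgeR's quasi-likelihood test.

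Of the antioxidant genes, Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, fell from 66.4 ± 1.65 to 29.3 ± 4.37 CPM (log2 fold change -1.18 ± 0.15, edgeR's quasi-likelihood adjusted p = 0.0434) and was the member of 24 that passed, over all genes and when adjusted over the list alone. Nqo1 at 0.43 ± 0.40, Gpx4 at -0.10 ± 0.20 and Sod2 at 0.49 ± 0.34 did not pass. In the inflammasome list, Txnip was the member that rose over all genes, and Il18, an interleukin that the inflammasome activates, fell when adjusted over the list alone. The apoptosis genes Bax at -0.52 ± 0.24 and Bcl2 at 0.05 ± 0.29 did not pass. Of 26 endoplasmic reticulum stress genes Manf was the member that fell over all genes, and 4 fell when adjusted over the list alone, Manf, Chac1, Sesn2 and Ddit3 (-1.18 ± 0.25), while Hspa5 at 0.22 ± 0.21 did not pass. That list had a mean of -0.23 and a median of 0.17, and camera gave an adjusted p of 0.758. Nlrp3 at -0.93 ± 0.60 and Il1b at -0.58 ± 0.63 did not pass. Cyp1a1, a target of the aryl hydrocarbon receptor, had 33 counts in PM2.5 library 2 and 0 in the other 5 libraries, Tnf had 10 counts in that library and 0 in the others, and Il6 had between 0 and 42 counts, so none of the 3 was tested. Cyp1b1 at -0.86 ± 0.71 did not pass.

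Of 6 measured erythroid markers 3 rose, and each of the 3 was higher in every PM2.5 library than in any control. Hba-a1, an alpha globin, rose from 506 ± 95.7 to 2178 ± 487 CPM, Hbb, a beta globin, rose from 165 ± 65.9 to 1287 ± 329 CPM, and Alas2, the heme synthesis enzyme of red cell precursors, rose from 2.87 ± 1.25 to 16.9 ± 2.61 CPM. They passed over all genes and when adjusted over the list alone, with edgeR's quasi-likelihood adjusted p between 0.0434 and 0.0463. Hba-a3, a copy similar to Hba-a1, had 201 and 183 CPM, and Ahsp 2.91 and 3.53 CPM, and neither passed. Camera gave the erythroid list an adjusted p of 4.05e-06 (adjusted p = 0.609 with an estimated correlation). Of the marker lists for other cell types with at least 5 tested members none was shifted. The camera adjusted p was 0.0853 for adipocytes, granulosa cells and oviduct epithelium and 0.0638 for ovarian surface epithelium and for oocytes. The neutrophil, mast cell, eosinophil and adrenal cortex lists had fewer tested members and were not tested as lists. The T and NK cell list, which holds Gzmb, had scores from 0.24 to 0.53 in the controls and from -0.41 to -0.28 in PM2.5, and did not pass (camera adjusted p = 0.147, fry adjusted p = 0.0713). The adipocyte gene Adipoq, as a measured fact, had 33.3 and 33.8 CPM in PM2.5 libraries 1 and 2 and between 0.929 and 2.60 CPM in the other 4.

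**Figure D3:**
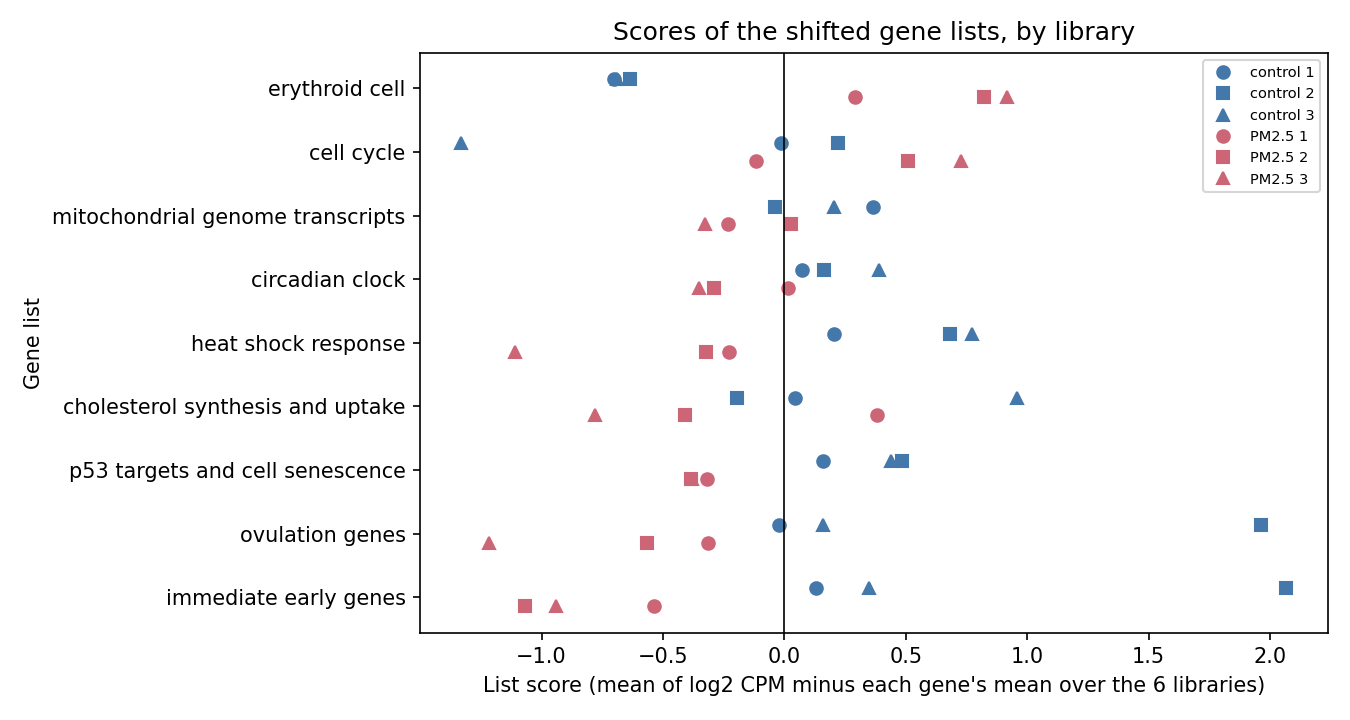
Score of each of the 9 lists that camera called with a preset correlation, by library, as the mean over members of log2 CPM minus each gene's mean over the 6 libraries. Circles, squares and triangles are replicates 1, 2 and 3 of each group. The erythroid scores lie between 0.29 and 0.92 in the PM2.5 libraries, and control 2 stands apart on the immediate early list at 2.07.

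Across all 49 lists, 45 had at least 5 tested members, 2 were higher and 7 lower, and 18 of 663 members changed over all genes, 4 higher and 14 lower. With 1 adjustment over all 663 members together, which is not the adjustment over each list alone given above, 33 changed, 6 higher and 27 lower. None of the 45 passed with an estimated correlation or with fry.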

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

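DESeq2, scaling by library size alone, counts divided by 4 and edgeR's own filter were chosen after the data were seen. The number of genes changed was 142 and stayed within 1.5 times of it, from 130 to 186, with other scalings, a mean of at least 1 FPKM, robust estimation, limma on log2 FPKM with pseudocounts of 1, 0.5 and 0.1, limma rescaled, without a trend or robust, library size alone and counts divided by 4. It was 8 without a filter, 87 with edgeR's own filter, 2983 with limma array weights and 1767 with DESeq2 (731 higher and 1036 lower), and the cause was not tested. Leaving out a library gave 0 to 7 genes, where fewer samples entered the test: 0 without control 1, 5 lower without control 2, 3 lower without control 3, 2 higher and 2 lower without PM2.5 library 1, 0 without PM2.5 library 2, and 6 higher and 1 lower without PM2.5 library 3. With edgeR, 1898 to 3493 genes still had an unadjusted p below 0.05 in those fits. In every setting run, each of the 142 genes that was tested kept its sign and an unadjusted p below 0.05. The sign was nearly fixed beforehand, since the groups did not overlap in any of the 142. The share of higher calls was 20.4%, and 41.4% with DESeq2 and 41.0% with array weights. The count at unadjusted p with a 2-fold difference was 1354, and was 674 with limma on log2(FPKM + 1), 670 with median-of-ratios scaling, 670 with quantile normalisation, 667 without a trend and 667 with robust estimation, where the pseudocount shrinks fold changes of low genes. The main screen had 525 higher and 829 lower, and with array weights 590 higher and 456 lower. The lists shifted numbered 9, 0 with an estimated correlation and 9 to 16 with a library left out. Genes changed within the lists numbered 18, 1 without a filter, 136 with array weights, 93 with DESeq2 and 0 to 1 with a library left out. The labels do not say whether same-numbered libraries were paired. Their deviations correlated at -0.177, 0.162 and 0.0932, which is too few values to settle it. With the replicate block, 1 gene changed, 14 lists shifted and 1 gene changed within the lists. With the replicate block in limma, 0 genes changed (2259 at an unadjusted p below 0.05), 787 passed the unadjusted screen and 0 changed within the lists. Of 5230 values for 210 named genes, none turned a called direction, 346 lost their call and 154 gained one. The clock list lost its call in each of the 9 limma settings (camera adjusted p from 0.064 to 0.142), the mitochondrial list with quantile normalisation (0.229) and array weights (0.0696), and the ovulation (0.0983) and p53 (0.0538) lists with array weights. At totals of 47662338 to 60749578 counts per library, edgeR recovered 8% of 2-fold changes in the simulated data.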

Other observations

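Several genes outside the naming rule also stood out and were chosen after their values were seen. Nkd2, an inhibitor of Wnt signalling, fell from 83.2 to 13.2 CPM and had the smallest adjusted p of all genes, 0.00843 in edgeR's quasi-likelihood test. Sdc1 and Igfbp3 fell too, with log2 fold changes of -1.90 and -2.83. Mpzl2 had no count in any control and 7.10 CPM on average in PM2.5, at least 117-fold higher against a floor of 3 counts per library. Loxl2 and Tgfb1, which the rule names, fell with log2 fold changes of -2.45 and -1.87, while the lists that hold them were not shifted. The extracellular matrix list had 15 of 29 members above the controls, with a median of 0.05 and a mean of -0.05 (camera adjusted p = 0.610), and the TGF-beta list had 16 of 20 above, with a median of 0.49 (camera adjusted p = 0.122). Among 317 pathways in the table's own annotation, the pathway of viral proteins that interact with cytokines and their receptors was lower (44 genes, median -0.62, camera adjusted p = 0.00226). DNA replication was higher (34 genes, median 0.37, camera adjusted p = 0.0219). Neither passed with an estimated correlation (adjusted p = 0.999 with an estimated correlation), and the pathways were not retested with a library left out. Pathways on the themes of other lists called above did not pass. These were Cell cycle (152 genes, median 0.24, camera adjusted p = 0.159), Steroid biosynthesis (17 genes, median -0.55, camera adjusted p = 0.176) and Circadian rhythm (30 genes, median 0.01, camera adjusted p = 0.860).

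With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 142 changed genes and the highest other split 0. For the unadjusted screen it gave 1354 and the highest other 703, and within the lists 18 against 0. For lists it gave 9 and the highest other split 18, with as many as the real split in 10 of 10 splits, so camera with a preset correlation also calls lists on structure among these samples that does not follow the exposure.

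For the patterns below, the tests of scaling, of a single library and of handling were chosen only after the result was seen. Of the tested members, 15 of 16 immediate early and 12 of 15 heat shock genes had negative fold changes, 2 and 4 passed over all genes, and neither list was shifted with an estimated correlation (adjusted p = 0.792 for each). A single library as the whole cause is argued against, since over the fits that leave out a library the mean log2 fold change nearest to 0 was -1.07 ± 0.28 (SE over members) for the immediate early genes, without control 2, and -0.87 ± 0.39 for the heat shock genes, without control 3. Control 2 did carry part of the immediate early shift, whose mean was -2.10 with all libraries, and members move together, so these SEs are too small. The heat shock mean also counts Hspa1b and its near-identical copy Hspa1a as 2 members, and the list median without control 3 was -0.35. The argument is therefore weaker for the heat shock genes. Handling or time to freezing at collection could lower the same genes, with 15 of 16 immediate early genes below the controls, and cannot be told apart from exposure because the labels give no collection order or times. An effect of the exposure stays open as well, and so do other differences between the samples that the labels do not give, which were not tested.

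In the clock list, Bmal1 was higher and Dbp, Per2 and Per3 lower when adjusted over the list alone, and none of these 4 passed over all genes. Bmal1 and Dbp kept opposite signs in 7 of 7 settings that vary the scaling between libraries, but the TMM factors of 0.963 to 1.04 are too close together to turn fold changes of this size, so that test decides nothing. A different phase of the daily clock at collection was a candidate explanation. A test set beforehand on 5 clock outputs outside the list (Usp2, Wee1, Tspan4, Lonrf3 and Nfil3) did not meet its prediction. The mean log2 fold change in the predicted direction was -0.63 ± 0.29 (SE over the 5 genes), with 1 of 5 in that direction. None of the 5 passed over all genes (edgeR's quasi-likelihood adjusted p of at least 0.0934), and this SE does not measure the spread between libraries. The test therefore goes against a different phase only weakly. It assumes textbook phases, and Usp2 at 1.20 and Lonrf3 at 1.43 carried most of it. An effect of the exposure stays open and was not tested separately.

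Hba-a1, Hbb and Alas2 were higher in every PM2.5 library, for which more red cell RNA may be the source. A test set beforehand predicted a PM2.5 to control ratio of at least 1.5 in the summed CPM of red cell genes outside the list. The ratio was 0.720, which goes against more red cell RNA by that rule. Fech, which other cells also express, made 94.2% of the sum in the controls. The test was set aside for this reason only after its result was seen, and it is taken to decide nothing. Without Fech the ratio was 1.13, on sums of 3.87 ± 1.54 and 4.37 ± 1.35 CPM (SD, n = 3), near the floor. Within the list, Hba-a3 and Ahsp did not rise with these genes and did not pass, as given above. More red cell RNA, a change in globin expression and the exposure itself cannot be told apart here.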
